A study of Mus musculus with 4 samples.

How the data were processed

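Live CD45+ cells from the aortas of Apoe-/- mice on a western diet for 13 weeks were sequenced with the 10x Genomics 3' chemistry, per the labels' protocols. Per the series text 6 mice were used; how they were divided over the 2 biological replicates is not given in the sources used here. The titles name 2 libraries for each replicate and do not say whether these hold different animals. The authors mapped reads to mm10 with Cell Ranger 3.0.2 and processed cells with Seurat 3.1.1, per the labels. Cell filters, doublet handling, clustering settings and names of clusters are not given in the sources used here. Only the cells that the authors kept as myeloid are deposited, so leukocytes of other kinds and cells they removed are not analysed here.

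The deposited count table holds raw UMI counts of 18825 genes in 3002 cells, of which 16087 genes have at least 1 count, 15893384 UMIs in all. The total counts deposited by the authors for each cell equal the sums of the table in all 3002 cells. The smallest cell held 502 UMIs, the fewest genes in a cell were 201, and the highest percent of mitochondrial counts deposited by the authors was 9.99. A second deposited table holds the natural log of 1 plus 10000 times the count over the total of the cell, within 1e-12; it was checked against the counts and not tested. The cell names carry the library, and the deposited cluster numbers of the authors, 0 to 13, were used as they are. Depth runs from 1698585 to 5954716 UMIs per library. Intervals and floors from counts cover counting error only.

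Biological replicate 1 held 1467 cells and 7653301 UMIs, and replicate 2 held 1535 cells and 8240083 UMIs. Raw counts were summed over the cells of a cluster in each biological replicate. The 6 macrophage and 3 dendritic clusters with at least 10 cells in each replicate gave 18 sums, fitted together with edgeR 4.0.16 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest) with a term per cluster and the biological replicate as a block, on 8 residual degrees of freedom and 5090 genes. The block stands because clusters of 1 replicate come from the same animals. Macrophage clusters were compared with dendritic clusters as means over clusters, and each cluster with the mean of the others of its class. Benjamini-Hochberg adjusted p values under 0.05 were called, and counts for single clusters also needed a log2 fold change of at least 1 in either direction; counts of list members needed the adjusted p value only. All tests are two-sided. The 2 replicates are few, and the spread is shared over the clusters.

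Levels are mean counts per 1e+06 counts (CPM) over 2 biological replicates, computed here from the deposited counts, with the mean over clusters where a class is described. A fitted log2 fold change averages log levels over clusters, so a cluster near 0 pulls it away from the ratio of the mean CPM. A gene with 0 counts in a cluster has no finite log level there, which can balance any other difference and leave an adjusted p of 1; 1119 of the 5090 tested genes had 0 counts in at least 1 compared cluster. Where a side had 0 counts, the fold is given against a floor of 3 counts over the group as at least that many times. With 1 to 3 counts it is a ratio of pooled counts with a 95% interval. Genes with near-identical copies whose reads the counting could split are uncertain, among them Lyz1 and Lyz2, Hspa1a and Hspa1b, the haemoglobin genes, Ear2, the Cd209 genes and the H2 genes. Coordinates are from GENCODE M21 on GRCm38, in which 18118 of the 18825 symbols were found.

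The comparisons, the alternatives, the lists and the rule for named genes were fixed before the data were examined. Named genes are the 10 highest and 10 lowest between the classes, and the 6 highest and 3 lowest of each cluster, by log2 fold change. They had to be called, move the same way in both replicates and reach at least 50 CPM on the higher side. The rule adds up to 4 called members of each list, the 7 markers in the series text and Apoe. Malat1 and Neat1 were named for the test of nuclear loss after the scarce inflammatory cytokine transcripts were seen and before their own levels were. Their comparison between the classes was added later. The markers quoted where clusters are named, and the leading genes of clusters outside the classes were chosen after their values were seen. Clusters were named X-like from marker lists fixed in the same way. Some markers are also in the function lists, and such lists are no separate support for a name. Clusters 3 and 8, whose median UMIs are far below those of their libraries, kept a name because 4 of its markers are among the 10 genes highest by fold. Other genes that lead cluster 3 are erythroid genes, from 1 cell. Clusters 5, 6, 7, 9 and 10 were left out of the classes and of the tests.

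Function lists were lipid uptake and efflux, cholesterol synthesis, lysosome, MHC class II, complement, inflammatory cytokines, interferon response, efferocytosis, matrix remodelling, iron handling, glycolysis, dissociation stress and cell cycle. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 3, limma-trend and a preset correlation of 0.01, adjusted over 130 pairs of list and comparison. Of these, 57 were called, and 0 with an estimated correlation. The cholesterol synthesis list, with 3 tested members, was called in none of the 10 comparisons. The test fry was run beside it: its PValue asks whether the genes of a set move on balance one way, its PValue.Mixed whether they change in either direction, and neither compares the set with other genes. No median of a called list changed sign with DESeq2 size factors or with DESeq2. Medians of lists that were not called did, with both in cluster 3 (efferocytosis, iron handling and glycolysis), and for cell cycle genes with size factors in cluster 2 and with DESeq2 in cluster 4.

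No doublet caller was run; an alternative removed the 5% of cells with the most UMIs in each library, 152 cells. Other alternatives were DESeq2 size factors, DESeq2 1.42.0 (Wald test), no filter on low counts, only genes with at least 50 CPM in a cluster, 4 libraries as samples with a library block, no replicate block, and leaving out each library. Thinning cells to 2000 UMIs left out 645, 302 in cluster 3 and 91 in cluster 8, so that fit lacks cluster 8. Count splitting assigned cells to the authors' clusters with 1 equal part of the thinned counts and tested genes with the other. It kept 90.4% of the cells in their cluster. Both parts had shaped these clusters, so double use of counts remains. A fit without clusters 3 and 8 was added after seeing the data. Thinning to 500 UMIs was random with a fixed seed and left out 0 cells. Intervals of shares of cells are exact (Clopper-Pearson) at 95%.

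In simulated data, 94.0% of genes with a log2 fold change of 1 were called in cluster 0, 67.2% in cluster 13 and 92.4% between classes. False calls were 3.69%, 2.22% and 5.83% of calls. These need not hold for real clusters, drawn from the tested counts. Software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.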

Results

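Leukocytes carrying CD45 were collected alive from the aortas of atherosclerotic Apoe-/- mice that had eaten a western diet for 13 weeks, and their RNA was counted by droplet-based 3' single-cell sequencing. Apoe-/- mice lack apolipoprotein E, which clears lipoprotein remnants from blood, and develop atherosclerotic plaques. The series text names 6 mice, and the sample titles name 2 biological replicates with 2 libraries each, all of 1 group. The deposited counts hold 3002 cells and 18825 genes, restricted to the cells that the series text calls myeloid, and the number of cells equals the number it states. Library 1-1 held 236 cells and 1698585 unique molecular identifiers (UMIs, each a captured transcript). Library 1-2 held 1231 cells and 5954716 UMIs, library 2-1 held 550 cells and 3668381 UMIs, and library 2-2 held 985 cells and 4571702 UMIs. The median cell held 6672 UMIs in library 1-1, 4301 in library 1-2, 6403.5 in library 2-1 and 4196 in library 2-2.

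All mice carried the same Apoe label, so the gene was read in each library as a check of that label. Apoe (chromosome 7, 19696109 to 19699188, minus strand, GRCm38) had 68 UMIs in library 1-1 (40.0 CPM), 217 in library 1-2 (36.4), 90 in library 2-1 (24.5) and 118 in library 2-2 (25.8). The labels do not say which part of the gene is deleted, and a 3' tag outside the deleted part checks nothing. Apoe reached 82.1 ± 30.99 CPM (SD, n = 2 biological replicates) in cluster 0 and 10.6 ± 1.93 in cluster 4. Between the macrophage and the dendritic clusters its log2 fold change was 0.84 ± 0.50 (SE, adjusted p = 0.194).

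The authors' 14 clusters are deposited as numbers, and lists of cell type markers gave 12 of them a name. Cluster 0 had 11 of 12 resident macrophage markers at least 2-fold above the mean of the other clusters, with the hyaluronan receptor gene Lyve1 at 771 ± 47.8 CPM (SD, n = 2 biological replicates). Its highest gene by fold, Jchain, had 603 UMIs, all from 1 cell, and the stress genes Jun, Egr1 and Hspa1b were among its 10 highest. Cluster 3 had 9 of the 12 resident markers at that level, among them the chemokine gene Ccl8 at 2894 ± 1132 CPM (SD, n = 2). In cluster 2, 8 of 12 inflammatory markers passed, beside 9 of 12 resident markers, with the chemokine gene Ccl2 at 3563 ± 68.1 CPM. Cluster 8 had 11 of 12 markers of foamy, lipid-laden macrophages, with Spp1 (osteopontin) at 10361 ± 251 and the lipid receptor gene Trem2 at 1299 ± 119. Cluster 13 had 6 of 10 markers of cavity macrophages, such as Retnla at 7889 ± 371. Cluster 1 carried macrophage markers but matched no subtype, with 2 of 12 foamy markers; it led with Cd72 at 653 ± 82.97 and the fractalkine receptor gene Cx3cr1 at 286 ± 21.6. Clusters 4, 11 and 12 matched dendritic cells of the cDC2, cDC1 and mature kinds with 8 of 8, 8 of 8 and 9 of 9 markers.

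Outside these classes lay cluster 5 (monocyte-like, 7 of 12 markers), cluster 6 (proliferation genes, 9 of 9), cluster 7 (neutrophil-like, 7 of 8), cluster 9 (fibroblast genes, 6 of 6) and cluster 10, which stayed unnamed. Cells of clusters 3, 8 and 10 were shallow, with median totals of 834, 980 and 805 UMIs against 4404 in cluster 0. The gate on CD45 should remove fibroblasts, yet the fibroblast gene Dcn (decorin) reached 12033 ± 1123 CPM in cluster 9 against 52.3 ± 10.3 in cluster 0 (SD, n = 2). In cluster 3, all but a few of the haemoglobin UMIs came from 1 cell, which held 3400 of 3433.

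**Figure D1:**
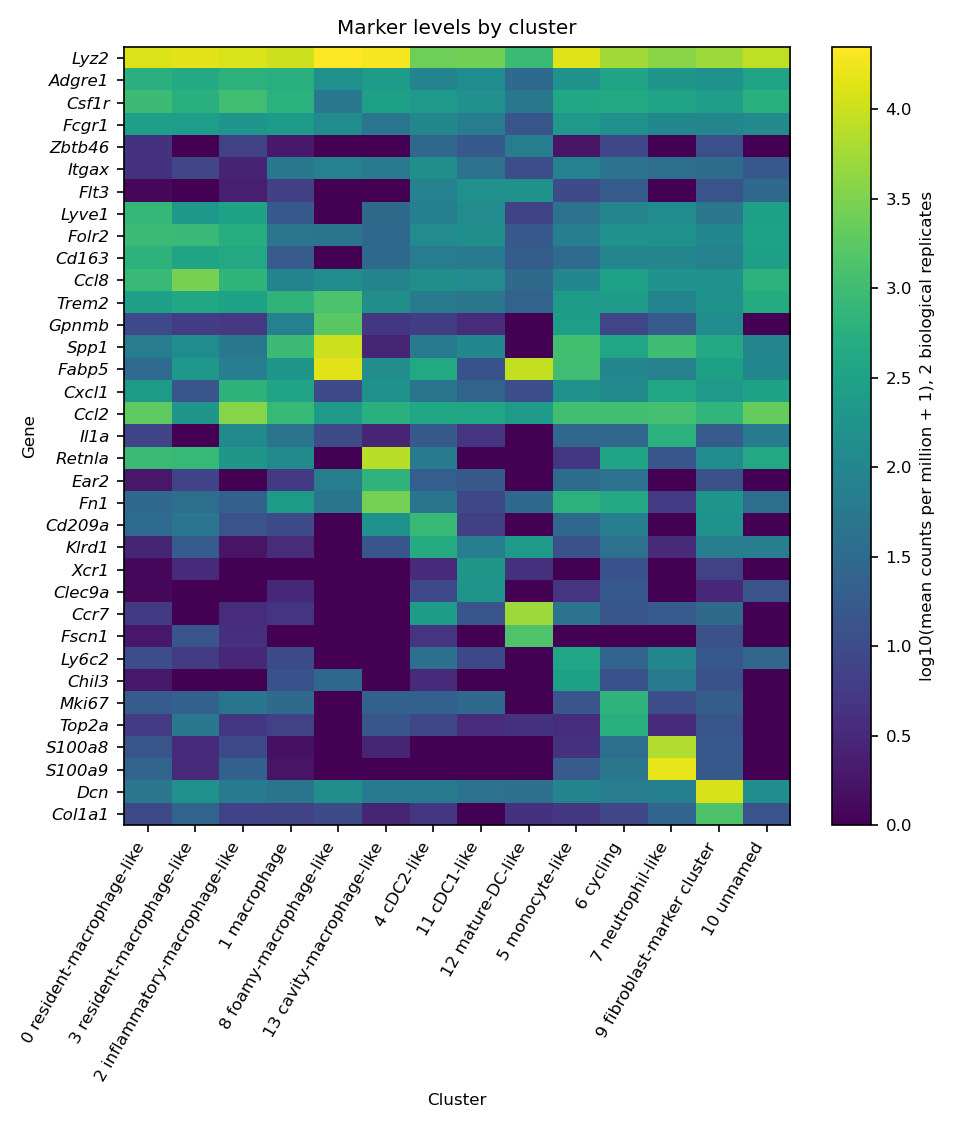
Level of 35 marker genes (vertical axis) in the 14 clusters (horizontal axis), as log10 of the mean CPM plus 1 over 2 biological replicates. Spp1 and Fabp5 are brightest in cluster 8, Lyve1 in cluster 0, Ccr7 and Fscn1 in cluster 12, and S100a8 and S100a9 in cluster 7.

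Macrophage clusters made up most of the myeloid cells. The 6 macrophage clusters held 67.4% ± 3.91 of the cells of a library (SD, n = 4 libraries; 1996 cells), the 3 dendritic clusters 11.7% ± 1.35 (367 cells) and the 5 other clusters 20.9% ± 3.14 (639 cells). Cluster 0 was largest on average, at 20.1% ± 4.70, then cluster 1 at 18.3% ± 3.76. In replicate 1 cluster 1 led, 20.7% to 18.2%. Clusters 2 and 3 held 11.6% ± 0.891 and 12.2% ± 4.07, from 347 and 325 cells. Cluster 8 held 3.84% ± 1.40 and cluster 13 held 1.30% ± 0.640. Among dendritic cells, cluster 4 held 8.80% ± 1.00, cluster 12 held 1.49% ± 0.517 and cluster 11 held 1.43% ± 0.441. Clusters 5, 6, 7, 9 and 10 held 7.0% ± 1.02, 3.94% ± 1.61, 4.03% ± 1.75, 3.38% ± 0.996 and 2.53% ± 0.174. With 1 group of mice no shares were compared between conditions, and the sort, the authors' filters and the depth of the cells can all set these shares. Among cells with at least 1000 detected genes, cluster 3 fell to 0.529%, cluster 8 to 0.242% and cluster 10 to 0.0782%.

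**Figure D2:**
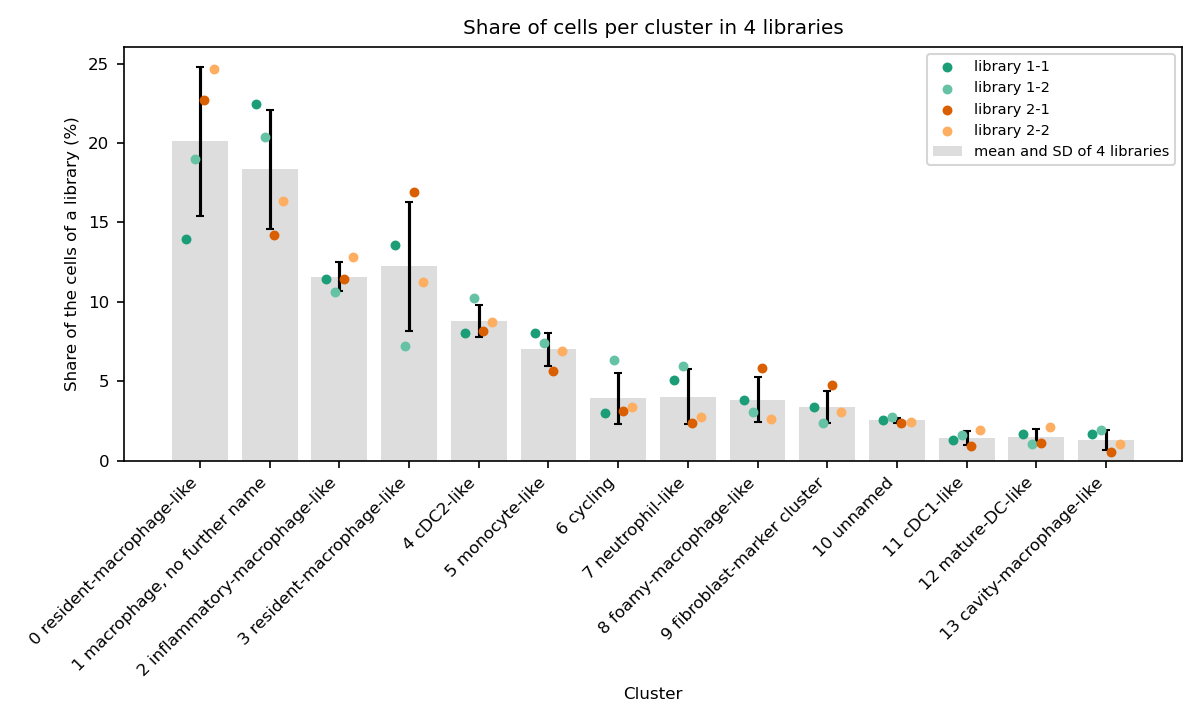
Share of the cells of a library (vertical axis, percent) in each of the 14 clusters (horizontal axis). Bars and error bars give the mean and SD of 4 libraries and points the libraries. Cluster 0 holds 20.1% and cluster 1 holds 18.3% on average.

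The series text sorts the myeloid cells into macrophages and dendritic cells by 7 markers, and these classes were compared. All 4 macrophage markers were higher in the macrophage clusters. Lyz2, which encodes lysozyme, had 15423 ± 1289 against 2017 ± 178 CPM in the dendritic clusters (SD, n = 2), a log2 fold change of 3.03 ± 0.10 (SE, adjusted p = 6.13e-19). Adgre1, the gene of F4/80, had 433 ± 22.4 against 83.2 ± 3.86, Csf1r, the receptor of macrophage growth factor, 583 ± 13.5 against 141 ± 0.889, and Fcgr1, a receptor for IgG, 194 ± 7.06 against 62.1 ± 21.7, with log2 fold changes of 2.39 ± 0.15, 1.88 ± 0.21 and 1.69 ± 0.25. All 3 dendritic markers were lower. Flt3, a growth factor receptor of dendritic cells, had 1.22 ± 0.0195 against 132 ± 18.03, and Zbtb46, a transcription factor of classical dendritic cells, 1.77 ± 1.35 against 37.05 ± 2.67. Itgax, the gene of CD11c, differed least, at 34.9 ± 0.852 against 66.6 ± 11.5 (log2 fold change -1.43 ± 0.49, adjusted p = 0.0206), and its log2 fold change was 0.70 (adjusted p = 0.967) without library 2-2. The study chose these 7 genes on the same cells. They and cluster markers such as Ccr7 are no independent evidence of the split. On GRCm38 the genes lie on chromosome 10 (Lyz2, 117277331 to 117282321), 17 (Adgre1, 57358691 to 57483527), 18 (Csf1r, 61100598 to 61132149), 3 (Fcgr1, 96282909 to 96293969), 5 (Flt3, 147330741 to 147400489), 2 (Zbtb46, 181387762 to 181459426) and 7 (Itgax, 128129547 to 128150657).

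Lpl, Fcgr4 and Cebpa were among the genes highest in macrophage clusters by log2 fold change. The lipoprotein lipase gene Lpl had 417 ± 38.8 against 16.9 ± 14.7 CPM in dendritic clusters (SD, n = 2), the IgG receptor gene Fcgr4 95.03 ± 24.9 against 19.7 ± 5.999, and Cebpa, a myeloid transcription factor, 182 ± 17.5 against 52.9 ± 4.77. Camk1, a calmodulin-dependent kinase gene, Hacd4, Tmem86a and Lyz1, a lysozyme gene near-identical to Lyz2 and therefore uncertain, had log2 fold changes of 4.26 ± 0.37, 4.44 ± 0.36, 4.19 ± 0.55 and 4.69 ± 0.72 (SE). The small heat shock protein gene Hspb1 had 5.56 ± 1.497, the proton pump subunit gene Atp6v0d2 5.45 ± 1.09 and the thrombospondin gene Thbs1 4.93 ± 1.89 (adjusted p = 0.0411). Dendritic clusters had more of the lymph node homing receptor gene Ccr7, at 1826 ± 35.5 against 1.78 ± 1.94 CPM, and of P2ry10, Klrd1, H2-Oa, H2-Eb2 and Il4i1, with log2 fold changes from -6.95 to -6.30. Btla, Spint2 and Cacnb3 had 2, 3 and 1 UMIs in all macrophage clusters, and pooled counts were 187-fold (95% interval 50.7 to 1560.3), 76.8-fold (95% interval 25.3 to 380.3) and 284-fold (95% interval 49.8 to 11338) higher in dendritic clusters. Single clusters carry several of these class means: cluster 12 that of Ccr7 (5218 ± 49.6 CPM), Il4i1 (762 ± 144), Spint2 (206 ± 47.4) and Cacnb3 (365 ± 9.17), and cluster 11 most of Btla (124 ± 15.5). Cluster 8 carries the mean of Atp6v0d2 (703 ± 67.6), and cluster 13 those of Lyz1 (2515 ± 1312) and most of Thbs1 (639 ± 165) and Lpl (1412 ± 106). The call of Ccr7 was lost without library 1-2 (-7.05, adjusted p = 1), as was that of Il4i1 (-5.75, adjusted p = 1). Those of Atp6v0d2 [4.43 (adjusted p = 1) without library 1-1, 5.38 (adjusted p = 1) without library 1-2] and Thbs1 [4.78 (adjusted p = 0.0573) without library 1-1, 3.35 (adjusted p = 1) without library 1-2, 4.25 (adjusted p = 1) without library 2-2] were lost as well. Between the classes, calls were lost at 2000 UMIs per cell for Hspb1 (4.64, adjusted p = 1), Thbs1 (3.21, adjusted p = 1), Lpl (5.16, adjusted p = 1), Il4i1 (-4.90, adjusted p = 1), Zbtb46 (-3.97, adjusted p = 0.0797), Itgax (-1.51, adjusted p = 0.121), Neat1 (-1.19, adjusted p = 0.441) and Btg2 (-0.31, adjusted p = 0.49); with count splitting for Il4i1 (-5.06, adjusted p = 1); without the 5% of cells with the most UMIs for Thbs1 (4.87, adjusted p = 0.124); without the replicate block for Thbs1 (4.98, adjusted p = 0.0762); with 4 libraries as samples for Atp6v0d2 (4.17, adjusted p = 1) and Thbs1 (4.61, adjusted p = 0.084); and with only genes at 50 CPM for Thbs1 (4.95, adjusted p = 0.0535).

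Genes of lysosomal breakdown, lipid handling, complement, iron and engulfment were higher together in the macrophage clusters. Of 17 tested lysosome genes 16 were higher and 0 lower, among them the protease genes Ctsd at 1736 ± 292 against 159 ± 46.6 and Ctsb at 3049 ± 487 against 583 ± 58.2 CPM (SD, n = 2). In the lipid uptake and efflux list 10 of 16 were higher, such as the lipid droplet coat gene Plin2 (1.99 ± 0.13) and the cholesterol exporter gene Abca1 (1.66 ± 0.17), and 1 was lower. Complement genes were higher in 7 of 9 cases (8 adjusted over the list alone), led by C1qb at 5774 ± 231 against 846 ± 234. Of 6 iron genes 5 were higher, including the haem oxygenase gene Hmox1 (1.85 ± 0.23) and the ferritin gene Ftl1 (1.496 ± 0.09), and of 12 engulfment (efferocytosis) genes 9 were higher, including Lrp1 (2.14 ± 0.29) and Stab1 (2.12 ± 0.30). In the matrix remodelling list 5 of 10 were higher and 1 lower, among them the inhibitor gene Timp2 (3.38 ± 0.16). All counts but that of complement were the same adjusted over the list alone. Median log2 fold changes were 1.33, 1.42, 1.61, 1.68, 1.61 and 1.49 in that order. Their camera adjusted p values were 2.76e-13, 0.000486, 1.1e-06, 6.73e-06, 3.17e-05 and 0.00449. The matrix list had adjusted p = 0.0811 with an estimated correlation, and each of the other 5 lists had adjusted p = 0.0529 with an estimated correlation. Further list members lost their calls without the libraries given or in other fits: Ciita (1 other), Axl (1 other), Spp1 (1-2, 3 others), Mmp12 (3 others), Fn1 (2-1).

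MHC class II genes were higher in the dendritic clusters. All 8 tested genes of MHC class II, which presents peptides to T cells, were lower in macrophage clusters (8 adjusted over the list alone), median log2 fold change -1.17 (adjusted p = 7.78e-05, and 0.158 with an estimated correlation). That median was -0.76 (adjusted p = 1.64e-05) without clusters 3 and 8. H2-Ab1 had 5225 ± 73.3 against 10382 ± 188 CPM and H2-DMb2, a chaperone gene of peptide loading, 7.77 ± 4.45 against 108 ± 8.73 (SD, n = 2). Of 12 dissociation stress genes, a list of immediate-early and heat shock genes that can be induced while tissue is digested, 11 were lower (11 adjusted over the list alone), median -0.69 (adjusted p = 0.00129, and 0.275 with an estimated correlation). Without clusters 3 and 8 that list went the other way, with a median of 0.86 (adjusted p = 2.89e-07), and its member Btg2 moved from -1.23 to 0.31. The inflammatory cytokine, interferon response, glycolysis, cell cycle and cholesterol synthesis lists were not called. The inflammatory cytokine list was called higher in macrophage clusters without clusters 3 and 8, with a median of 1.65 (adjusted p = 0.00166) against -0.25 with them. Single members still differed, such as Il1b, the gene of interleukin 1 beta, at 982 ± 217 against 3085 ± 78.4. Of the nuclear RNAs, whose comparison between the classes was added after their levels by cluster were seen, Malat1 had 12530.0 ± 560.1 against 18685 ± 524 and a log2 fold change of -1.58 ± 0.14, but 0.02 without clusters 3 and 8. Neat1 moved from -0.84 to 0.89 in the same way.

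In total 739 genes were higher and 1200 lower in the macrophage than in the dendritic clusters among 5090 tested genes (edgeR quasi-likelihood test, 18 sums). Without clusters 3 and 8, left out after the data were seen, 1568 genes were higher and 1099 lower among 8224, and 41 of the genes called in both fits had opposite signs. Of the genes also tested in that fit, 603 of 737 kept the call higher and 799 of 1200 the call lower. The counts were 466 higher and 898 lower without library 1-2 and 508 higher and 736 lower without library 2-2. Of the 84 ways to divide the 9 clusters into 6 and 3, 16 gave at least 1939 genes in all, the real one included.

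The series is about how macrophages of the diseased aorta differ among themselves, so each macrophage cluster was set against the mean of the other 5. Medians given for lists are of log2 fold changes. The clusters were drawn from the same counts, so their genes describe them and p-values, also between classes, are too small. Dissociation stress transcripts varied widely between clusters and are given with each of them. At 500 UMIs per cell the 12 stress genes made up 5.80% of the UMIs of cluster 0 in replicate 1 and 5.86% in replicate 2. They made up 0.215% and 0.0824% in cluster 3, and 0.0681% and 0.0517% in cluster 8. With no thinning these shares were 5.27% and 5.66% in cluster 0, 0.172% and 0.0797% in cluster 3, and 0.0619% and 0.0560% in cluster 8. The nuclear RNA Malat1 (chromosome 19, 5795690 to 5802672, minus strand, GRCm38) had 21559 ± 91.4 CPM (SD, n = 2) in cluster 0, 1117 ± 987 in cluster 3 and 389 ± 145 in cluster 8. No Malat1 UMI was found at 500 UMIs per cell in 89.5% of the cells of cluster 3 (exact 95% interval 85.7% to 92.6%) and 93.3% of those of cluster 8 (86.7% to 97.3%), against 1.42% in cluster 0 (0.650% to 2.67%). With no thinning it was 84.3%, 86.7% and 0.157% of the cells in the same order. Since clusters 3 and 8 enter the mean of the others, the counts of clusters 0, 1, 2 and 13 are also given without them.

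**Figure D3:**
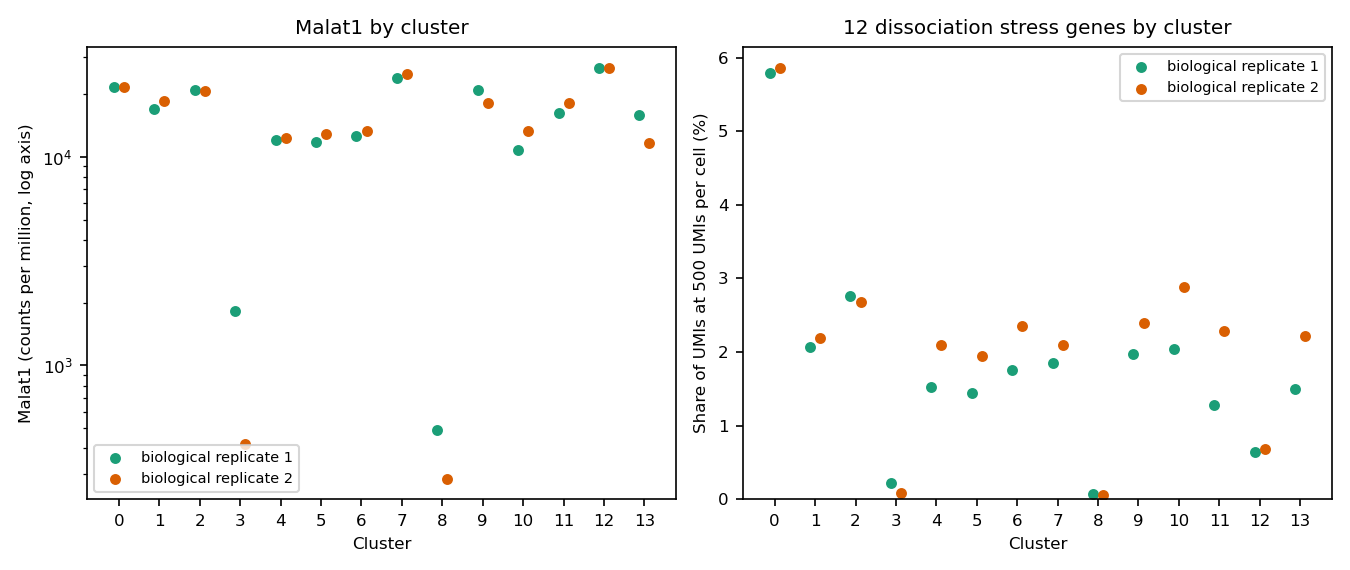
Left, Malat1 in CPM (vertical log axis) by cluster. Right, share of UMIs (vertical axis, percent) in 12 dissociation stress genes with every cell thinned to 500 UMIs. Points are 2 biological replicates. Clusters 3 and 8 lie lowest in both panels, with stress shares from 0.0517% to 0.215%, and cluster 0 has the highest stress shares.

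Cluster 0, resident-macrophage-like, had more transcripts of the receptor genes Lyve1, Timd4 and Cd163. Lyve1 (chromosome 7, 110850607 to 110863239, minus strand, GRCm38) had 771 ± 47.8 against 115 ± 19.3 CPM in the other macrophage clusters (SD, n = 2), and Timd4, a receptor for dying cells, 59.1 ± 15.2 against 10.8 ± 0.667. The haemoglobin scavenger gene Cd163 had 639 ± 53.4 against 163 ± 19.8. Adam33, Cmah, Cd209f and Hspa1b also ranked highest, with log2 fold changes of 6.16 ± 0.53, 4.85 ± 0.44, 5.03 ± 0.40 and 5.20 ± 0.22 (SE). Hspa1a and Hspa1b are near-identical copies and the Cd209 genes are a family, so reads could be split and their single values are uncertain. Fabp5, a fatty acid carrier gene, had 32.7 ± 20.96 against 2914 ± 4.09, the elastase gene Mmp12 6.70 ± 4.42 against 204 ± 26.8, and Il7r 1.84 ± 0.284 against 62.9 ± 13.4. Cluster 8 carries most of the mean of the others for Fabp5, at 13969 ± 168, and for Mmp12, at 685 ± 61.1, while Fabp5 had 196 ± 81.1, 69.99 ± 47.5, 203 ± 80.8 and 133 ± 21.3 in clusters 1, 2, 3 and 13. The call of Il7r was lost without library 2-2 (-2.19, adjusted p = 1). At 2000 UMIs, without cluster 8, calls of Il7r (-2.20, adjusted p = 0.979) and Mmp12 (-1.26, adjusted p = 0.344) were lost. Count splitting lost that of Il7r (-2.49, adjusted p = 1).

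In cluster 0 all 12 dissociation stress genes were higher (12 adjusted over the list alone), median 3.16 (adjusted p = 4.48e-15, and 0.0542 with an estimated correlation), with the immediate-early gene Jun at 7623 ± 634 against 978 ± 96.96 CPM (SD, n = 2). Of the complement genes, 7 of 9 tested members were higher and 0 lower (8 and 0 adjusted over the list alone), median 0.79 (adjusted p = 0.00424, and 0.111 with an estimated correlation), among them C4b (2.86 ± 0.21). Of the interferon response genes, 9 of 14 tested members were higher and 0 lower (11 and 0 adjusted over the list alone), median 1.55 (adjusted p = 0.00686, and 0.22 with an estimated correlation), and the antiviral gene Rsad2 had 103 ± 45.8 against 17.4 ± 3.67, with 43.0% of its UMIs from 1 cell. Of the glycolysis genes, 1 of 10 tested members were higher and 8 lower (1 and 8 adjusted over the list alone), median -0.86 (adjusted p = 4.96e-06, and 0.1 with an estimated correlation), such as Gapdh (-0.95 ± 0.13). Of the matrix genes, 2 of 10 tested members were higher and 5 lower (2 and 6 adjusted over the list alone), median -1.86 (adjusted p = 0.0104, and 0.0984 with an estimated correlation). Among the MHC class II genes, 0 of 8 tested members were higher and 4 lower (0 and 5 adjusted over the list alone), median -0.43 (adjusted p = 0.00686, and 0.27 with an estimated correlation). Of the inflammatory cytokine genes, 10 of 15 tested members were higher and 0 lower (10 and 0 adjusted over the list alone), median 1.91 (adjusted p = 0.00385, and 0.158 with an estimated correlation). Among the lysosome genes, 3 of 17 tested members were higher and 6 lower (3 and 6 adjusted over the list alone), median -0.17 (adjusted p = 0.0136, and 0.3 with an estimated correlation). Medians without clusters 3 and 8 were 1.47 (adjusted p = 1.78e-24) for stress genes and -1.10 (adjusted p = 1.44e-13) for MHC class II. The cytokine and lysosome lists lost their calls there, with medians of -0.19 (adjusted p = 0.171) and -0.16 (adjusted p = 0.712). The chemokine gene Cxcl2, with 10873 ± 565 against 7081 ± 359, moved from 2.56 to 0.04. Called higher in that fit alone were efferocytosis at 0.96 (adjusted p = 0.0121) and iron handling at 0.68 (adjusted p = 0.00769). Cluster 0 list members lost their calls without the libraries given or in other fits: Atp6v0d2 (1-1, 1-2, 2 others), Ctsd (1 other), H2-Eb1 (1-2, 2-1), H2-Aa (1-2, 2-1), H2-DMa (1-1, 1-2, 7 others), Tnfaip3 (1 other), Tnf (1 other), Adam8 (2-2, 2 others), Fn1 (2-1, 1 other), Timp2 (1-2), Hk2 (1-2, 2 others), Pfkp (2-1, 1 other). In all, cluster 0 had 1107 genes higher and 103 lower, and 480 and 236 without clusters 3 and 8.

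Cluster 1 had more MHC class II and Vegfa transcripts than the mean of the others. H2-Eb1 had 8825 ± 576 against 4782 ± 177 CPM (SD, n = 2). Among the MHC class II genes, 7 of 8 tested members were higher and 0 lower (7 and 0 adjusted over the list alone), median 1.05 (adjusted p = 0.000204, and 0.176 with an estimated correlation). The vessel growth factor gene Vegfa had 104 ± 36.4 against 14.4 ± 4.60, and Dusp5, a MAP kinase phosphatase gene, 111 ± 20.2 against 25.4 ± 7.09. Grasp and Plac8 also ranked highest, with log2 fold changes of 4.22 ± 0.42 and 4.70 ± 0.76 (SE). Tnfsf9, with 259 ± 3.12 against 151 ± 25.4, moved from 4.36 to 0.37 without clusters 3 and 8. Among lower genes, Ccl8 had 88.97 ± 18.1 against 938 ± 232, with most of the latter from cluster 3, Ccl24 7.85 ± 6.06 against 147 ± 64.7, and the folate receptor gene Folr2 49.6 ± 12.9 against 473 ± 6.04. The calls of Ccl24 (-2.31, adjusted p = 1) and Folr2 (-0.93, adjusted p = 0.994) were lost without library 1-2.

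Of the inflammatory cytokine genes in cluster 1, 14 of 15 tested members were higher and 0 lower (14 and 0 adjusted over the list alone), median 2.29 (adjusted p = 2.39e-11, and 0.0529 with an estimated correlation). Il1b had 3137 ± 396 against 551 ± 181 CPM (SD, n = 2) and the inflammasome sensor gene Nlrp3 at 426 ± 65.7 against 148 ± 20.03. Of the stress genes, 12 of 12 tested members were higher and 0 lower (12 and 0 adjusted over the list alone), median 1.60 (adjusted p = 1.1e-10, and 0.0867 with an estimated correlation). Among the iron genes, 1 of 6 tested members were higher and 3 lower (2 and 3 adjusted over the list alone), median -0.63 (adjusted p = 0.0147, and 0.131 with an estimated correlation). Hmox1 had 159 ± 0.270 against 469 ± 31.1. Without clusters 3 and 8 the medians were 0.67 (adjusted p = 3.9e-05) for MHC class II, 0.33 (adjusted p = 0.122) for cytokines, -0.25 (adjusted p = 5.87e-07) for stress genes and -0.07 (adjusted p = 0.202) for iron genes, so that the stress list turned and the cytokine and iron lists lost their calls. Lists called higher in that fit alone were lysosome at 0.46 (adjusted p = 3.45e-05), lipid at 0.52 (adjusted p = 0.00134), matrix at 1.30 (adjusted p = 0.00384) and glycolysis at 0.34 (adjusted p = 0.0132). Cluster 1 list members lost their calls without the libraries given or in other fits: Tnfaip3 (1 other), Blvrb (1-2, 2 others), Ftl1 (2 others), Slc11a1 (1 other), Hspa1b (1 other), Hspa1a (1 other), Fosb (1 other), Fos (1 other). In all, cluster 1 had 869 genes higher and 40 lower, and 363 and 154 without clusters 3 and 8.

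Cluster 2, inflammatory-macrophage-like, had more cytokine and chemokine transcripts. Every marker behind that name except Ier3 is also in the inflammatory cytokine list. The result of that list therefore repeats the naming and is no separate support for it. Il1a, the gene of interleukin 1 alpha, had 113 ± 13.1 against 12.8 ± 3.85 CPM (SD, n = 2), Tnfaip3, a brake of NF-kappaB signalling, 973 ± 148 against 249 ± 38.3, and Hbegf, a growth factor gene, 214 ± 55.3 against 20.8 ± 10.2. Of the inflammatory cytokine genes, 13 of 15 tested members were higher and 0 lower (13 and 0 adjusted over the list alone), median 3.14 (adjusted p = 2.38e-09, and 0.0529 with an estimated correlation), a median that was 1.42 (adjusted p = 2.73e-11) without clusters 3 and 8. Tnfsf9, Gpr84, Adam33 and Apold1 also ranked highest, with log2 fold changes of 5.33 ± 0.42, 5.06 ± 0.54, 5.77 ± 0.64 and 4.86 ± 0.64 (SE). Ear2, a ribonuclease gene with near-identical relatives and an uncertain level, had no UMI, at least 21.2-fold lower than in the other macrophage clusters. Mmp12 had 6.40 ± 3.42 against 205 ± 28.4, and S100a4, a calcium-binding protein gene, 33.7 ± 8.69 against 318 ± 9.14. Most of the mean of the others comes from cluster 13 for Ear2, at 672 ± 143, and from cluster 8 for Mmp12, at 685 ± 61.1. In cluster 2, calls were lost at 2000 UMIs per cell for Ear2 (-4.76, adjusted p = 1).

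Of the complement genes in cluster 2, 6 of 9 tested members were higher and 1 lower (6 and 1 adjusted over the list alone), median 1.44 (adjusted p = 0.0136, and 0.158 with an estimated correlation). With DESeq2 that median was 0.82. The anaphylatoxin receptor gene C5ar1 had 341 ± 21.01 against 131 ± 2.96 CPM (SD, n = 2). Of the glycolysis genes, 1 of 10 tested members were higher and 8 lower (1 and 9 adjusted over the list alone), median -0.93 (adjusted p = 1.19e-05, and 0.109 with an estimated correlation), where Gapdh had 372 ± 14.98 against 858 ± 37.6 and the hexokinase gene Hk2 was the higher member, at 113 ± 12.4 against 39.3 ± 4.91. Of the stress genes, 12 of 12 tested members were higher and 0 lower (12 and 0 adjusted over the list alone), median 2.04 (adjusted p = 1.13e-08, and 0.108 with an estimated correlation). Among the lysosome genes, 4 of 17 tested members were higher and 9 lower (4 and 9 adjusted over the list alone), median -0.42 (adjusted p = 0.00255, and 0.246 with an estimated correlation). Among the matrix genes, 1 of 10 tested members were higher and 3 lower (1 and 3 adjusted over the list alone), median -0.38 (adjusted p = 0.0316, and 0.131 with an estimated correlation). Without clusters 3 and 8 these last 3 lists lost their calls, with medians of -0.01 (adjusted p = 0.827), -0.12 (adjusted p = 0.55) and -0.12 (adjusted p = 0.191). The MHC class II list gained a call, lower, at -0.55 (adjusted p = 4.14e-07), and called higher in that fit alone were efferocytosis at 1.09 (adjusted p = 0.00365) and iron handling at 0.52 (adjusted p = 0.000308). Cluster 2 list members lost their calls without the libraries given or in other fits: Atp6v0d2 (1-1, 1-2, 2 others), Psap (1 other), Ctss (1 other), Adam8 (2-2, 2 others), Tpi1 (1 other), Fosb (1 other), Egr1 (1 other). In all, cluster 2 had 1072 genes higher and 160 lower, and 409 and 165 without clusters 3 and 8.

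Cluster 3, resident-macrophage-like and shallow, had few chemokine and immediate-early transcripts. Cxcl2 had 250.2 ± 187 against 9206 ± 283 CPM in the other macrophage clusters (SD, n = 2), Jun 110.3 ± 62.7 against 2481 ± 236 and the heat shock gene Hspa1a 38.6 ± 14.5 against 1805 ± 282. Of the inflammatory cytokine genes, 0 of 15 tested members were higher and 8 lower (0 and 9 adjusted over the list alone), median -2.49, or -2.31 with genes without counts on a side at their bound (adjusted p = 2.02e-08, and 0.0529 with an estimated correlation). Among the stress genes, 0 of 12 tested members were higher and 11 lower (0 and 11 adjusted over the list alone), median -3.25 (adjusted p = 2.65e-13, and 0.0673 with an estimated correlation). The chemokine receptor gene Cxcr4, Klf10 and Runx3 had no UMI, and were at least 20.96-fold, 12.1-fold and 8.88-fold lower than in the other macrophage clusters. The call of Cxcr4 was lost without library 2-1 (-7.58, adjusted p = 1), and that of Klf10 without library 1-2 (-6.86, adjusted p = 1). Of the lipid genes, 0 of 16 tested members were higher and 3 lower (1 and 6 adjusted over the list alone), median -0.76 (adjusted p = 0.0203, and 0.122 with an estimated correlation). Lpl had 71.3 ± 14.2 against 486 ± 49.3.

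Several complement, interferon response and cell cycle genes were higher in cluster 3. Cd209f and Cd209g had 174 ± 19.01 against 48.9 ± 19.8 and 77.8 ± 16.6 against 22.2 ± 7.44 CPM (SD, n = 2), and the growth factor gene Gas6, a bridge to dying cells, 669 ± 47.9 against 221 ± 37.95. Of the complement genes, 6 of 9 tested members were higher and 1 lower (6 and 1 adjusted over the list alone), median 0.86 (adjusted p = 0.0456, and 0.22 with an estimated correlation). C4b had 338 ± 41.4 against 198 ± 1.46. Among the interferon response genes, 6 of 14 tested members were higher and 0 lower (6 and 0 adjusted over the list alone), median 1.17 (adjusted p = 0.0191, and 0.268 with an estimated correlation), and the median was 0.92 with DESeq2 size factors and 0.45 with DESeq2. The tetherin gene Bst2 had 933 ± 180.4 against 492 ± 61.2. Of the cell cycle genes, 6 of 10 tested members were higher and 0 lower (8 and 0 adjusted over the list alone), median 2.44 (adjusted p = 5.13e-05, and 0.0845 with an estimated correlation), where Ube2c rested on 28 UMIs in 15 cells, Birc5 on 19 UMIs and Top2a on 18 UMIs in 7 cells. The highest gene, Ccl17 (8.77 ± 0.72, SE), rested on 46 UMIs in 3 cells. In all, cluster 3 had 309 genes higher and 279 lower, but 153 higher and 394 lower with DESeq2 size factors, which shifted the median of all genes by -0.26. In cluster 3, calls were lost at 2000 UMIs per cell for Cd209f (3.22, adjusted p = 0.0708), Ube2c (4.70, adjusted p = 0.342), Cd209g (2.08, adjusted p = 0.626), Top2a (3.34, adjusted p = 0.475), Klf10 (-7.76, adjusted p = 0.119), Runx3 (-6.95, adjusted p = 0.342) and C4b (0.17, adjusted p = 1); and with count splitting for Klf10 (-2.40, adjusted p = 0.0977). Cluster 3 list members lost their calls without the libraries given or in other fits: Abca1 (2-1, 2 others), Plin2 (1-1, 2-2, 2 others), C3ar1 (1 other), Tnf (1-1, 1-2, 1 other), Nfkbiz (2-1, 1 other), Cxcl1 (1-2, 1 other), Ifit3 (1 other), Zbp1 (2-2, 2 others), Phf11b (2 others), Fosb (2-1, 1 other).

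Cluster 8, foamy-macrophage-like and shallow, carried lipid and lysosome transcripts. The foamy markers include Fabp5, Lpl and Abcg1 of the lipid list and Ctsd and Atp6v0d2 of the lysosome list. They also include Spp1 and Mmp12 of the matrix list. The results of these lists are therefore not separate support for the name. Spp1 (chromosome 5, 104435118 to 104441050, plus strand, GRCm38) had 10361 ± 251 against 239 ± 65.3 CPM in the other macrophage clusters (SD, n = 2), the membrane glycoprotein gene Gpnmb 1722 ± 216 against 20.6 ± 0.699, and Fabp5 13969 ± 168 against 127 ± 41.8. Cd5l, a secreted scavenger protein gene, had 1283 ± 502 against 5.54 ± 4.04, Syngr1 626 ± 16.1 against 8.73 ± 1.42, and the neuropeptide gene Npy 171 ± 67.6 against 1.41 ± 1.61 from 21 UMIs. Hal had 13 UMIs in cluster 8 and 2 in the other clusters, a pooled ratio of 443-fold (95% interval 100.3 to 4042). Of the lysosome genes, 12 of 17 tested members were higher and 1 lower (15 and 1 adjusted over the list alone), median 1.501 (adjusted p = 4.02e-10, and 0.0646 with an estimated correlation). The proton pump gene Atp6v0d2 had 703 ± 67.6 against 9.65 ± 3.66 and the protease gene Ctsl at 5228 ± 907 against 338 ± 45.1. Of the lipid genes, 7 of 16 tested members were higher and 1 lower (8 and 1 adjusted over the list alone), median 0.65 (adjusted p = 0.00258, and 0.0766 with an estimated correlation). Among the matrix genes, 4 of 10 tested members were higher and 1 lower (5 and 1 adjusted over the list alone), median 1.79 (adjusted p = 0.00977, and 0.0984 with an estimated correlation). In cluster 8, calls were lost with DESeq2 for Hal (7.64, no adjusted p) and Npy (7.51, adjusted p = 0.237); and with count splitting for Hk2 (-6.96, adjusted p = 0.0863).

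MHC class II and inflammatory cytokine genes were low in cluster 8. The mannose receptor gene Mrc1, Retnla and Hspa1b had no UMI, and were at least 45.8-fold, 34.7-fold and 62.8-fold lower than in the other macrophage clusters, where cluster 13 had most of Retnla, at 7889 ± 371 CPM. H2-Ab1 had 1017 ± 492 against 6067 ± 186 CPM (SD, n = 2). Among the MHC class II genes, 0 of 8 tested members were higher and 6 lower (0 and 7 adjusted over the list alone), median -2.49, or -2.32 with genes without counts on a side at their bound (adjusted p = 0.00288, and 0.247 with an estimated correlation). Of the inflammatory cytokine genes, 0 of 15 tested members were higher and 12 lower (0 and 12 adjusted over the list alone), median -4.37, or -4.05 with genes without counts on a side at their bound (adjusted p = 0.000228, and 0.0984 with an estimated correlation), with Tnfaip3 and Nlrp3 without a UMI and at least 22.02-fold and 12.8-fold lower. Of the stress genes, 0 of 12 tested members were higher and 12 lower (0 and 12 adjusted over the list alone), median -5.31 (adjusted p = 3.41e-07, and 0.131 with an estimated correlation). Zfp36 had 31.9 ± 6.43 against 3187 ± 82.4. Of the glycolysis genes, 5 of 10 tested members were higher and 1 lower (6 and 1 adjusted over the list alone), median 0.76 (adjusted p = 0.000879, and 0.187 with an estimated correlation), with a mean of -0.10, since the lower member, Hk2, had no UMI. The call of Hk2 was lost without library 1-2 (-7.75, adjusted p = 0.077). In all, cluster 8 had 295 genes higher and 948 lower. DESeq2 size factors shifted the median of all genes in it by 0.11. Cluster 8 list members lost their calls without the libraries given or in other fits: Nr1h3 (1 other), Mmp14 (1-2). Counts were 235 higher and 545 lower without library 2-1, and fewer lower without library 1-2, with 1 sum left.

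Cluster 13, cavity-macrophage-like, had more MHC class II and Fn1 transcripts. The fibronectin gene Fn1 had 2741 ± 63.7 against 74.2 ± 0.641 CPM (SD, n = 2), Ear2 672 ± 143 against 15.5 ± 7.63, the adhesion receptor gene Cd226 111 ± 5.83 against 0.924 ± 0.171, and the calcium channel gene Ryr1 84.3 ± 20.3 against 3.31 ± 0.632. Wnt11 had 78.8 ± 28.1 against 1.30 ± 0.329, and Upb1 and Bcam, with 1 UMI each in the other clusters, had pooled ratios of 625-fold (95% interval 104 to 25511) and 603-fold (95% interval 99.7 to 24660.1). Of the MHC class II genes, 8 of 8 tested members were higher and 0 lower (8 and 0 adjusted over the list alone), median 1.67 (adjusted p = 7.84e-07, and 0.0984 with an estimated correlation). The loading gene H2-DMb1 had 1074 ± 212 against 291 ± 18.1. Of the glycolysis genes, 6 of 10 tested members were higher and 0 lower (9 and 0 adjusted over the list alone), median 0.71 (adjusted p = 0.0023, and 0.22 with an estimated correlation). Ldha had 399 ± 28.1 against 180.3 ± 5.26. Of the stress genes, 9 of 12 tested members were higher and 0 lower (11 and 0 adjusted over the list alone), median 1.35 (adjusted p = 2.88e-05, and 0.199 with an estimated correlation), and this list turned without clusters 3 and 8, with a median of -1.02 (adjusted p = 5.72e-08) and Fosb at -0.59 against 1.97. The cytokine list, not called with a median of 0.81, was called lower in that fit, at -1.51 (adjusted p = 6.33e-06).

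Most complement, most iron and some engulfment genes were low in cluster 13. C1qa had 1229 ± 64.2 against 6513 ± 286 CPM (SD, n = 2), Gas6 16.6 ± 23.4 against 351 ± 52.2 and Blvrb, a haem breakdown enzyme gene, 85.4 ± 51.1 against 490.2 ± 26.5. Of the complement genes, 1 of 9 tested members were higher and 7 lower (1 and 7 adjusted over the list alone), median -1.57 (adjusted p = 9.57e-06, and 0.0529 with an estimated correlation). Among the engulfment genes, 1 of 12 tested members were higher and 5 lower (1 and 5 adjusted over the list alone), median -1.42, or -1.21 with genes without counts on a side at their bound (adjusted p = 0.000899, and 0.0867 with an estimated correlation). Among the iron genes, 0 of 6 tested members were higher and 4 lower (0 and 4 adjusted over the list alone), median -0.94 (adjusted p = 6.29e-05, and 0.0529 with an estimated correlation). Of the lysosome genes, 2 of 17 tested members were higher and 7 lower (3 and 7 adjusted over the list alone), median -0.40 (adjusted p = 0.000256, and 0.177 with an estimated correlation), a call that was lost without clusters 3 and 8, where the median was -0.29 (adjusted p = 0.202). Of the interferon response genes, 0 of 14 tested members were higher and 4 lower (0 and 4 adjusted over the list alone), median -0.95, or -0.66 with genes without counts on a side at their bound (adjusted p = 5.13e-05, and 0.1 with an estimated correlation). Bst2 had 206 ± 0.555 against 637 ± 25.02. Ms4a7 had 46.2 ± 39.3 against 766 ± 72.5, Spp1 had 1 UMI, with a pooled ratio of 216-fold (95% interval 38.8 to 8538) for the other clusters, mostly from cluster 8, and the ceruloplasmin gene Cp had none, at least 7.03-fold lower. The call of Cp was lost without library 1-2 (-7.28, adjusted p = 0.0969) and without library 2-1 (-6.14, adjusted p = 1). With clusters 3 and 8 left out, medians were 1.02 (adjusted p = 2.32e-08) for MHC class II, -2.38 (adjusted p = 4.03e-06) for complement and -1.46 (adjusted p = 3.96e-05) for interferon genes. In cluster 13, calls were lost with DESeq2 for Bcam (7.04, adjusted p = 0.307); at 2000 UMIs per cell for Cp (-6.32, adjusted p = 0.204) and Fosb (0.36, adjusted p = 0.86); and with count splitting for Cp (-5.58, adjusted p = 1). Cluster 13 list members lost their calls without the libraries given or in other fits: Ciita (1-2, 2 others), C5ar1 (2-1), C4b (2-1), Ifi204 (1 other), Irf7 (1-1, 1-2, 2-1, 2-2, 5 others), Mfge8 (1-2, 2 others), Slc11a1 (1-1, 1-2, 2-1, 2-2, 5 others), Hk2 (1-2, 2 others), Eno1 (1-2, 1 other), Pgam1 (1-2, 2 others). Cluster 13 had 616 genes higher and 221 lower, 458 and 598 without clusters 3 and 8, and fewer without library 1-2, with 1 sum left.

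Each of the 3 dendritic clusters was set against the mean of the other 2, again as a description. Cluster 4, cDC2-like, had more of the lectin gene Cd209a, at 838 ± 33.96 CPM (SD, n = 2) and a pooled ratio of 194-fold (95% interval 66.4 to 943) over 3 UMIs in the others. Plaur, the urokinase receptor gene, had 219 ± 19.00 against 9.69 ± 10.1, and Areg, a growth factor gene, had 1 UMI in the others and a pooled ratio of 43.01-fold (95% interval 7.59 to 1711). Retnla, Thbs1 and the fatty acid receptor gene Ffar2 had no UMI in the others and were at least 14.3-fold, 13.9-fold and 11.9-fold higher. Retnla came from 11 of 276 cells, and its call was lost without library 1-2 (7.44, adjusted p = 0.101) and without library 2-2 (7.73, adjusted p = 0.0657). Il1b had 5519 ± 185 against 1867 ± 210.0. The T cell costimulator gene Tnfrsf4 had no UMI in cluster 4, at least 61.8-fold lower, while Il12b had 1 UMI and Ly75 had 2, with pooled ratios of 156-fold (95% interval 26.7 to 6298) and 63.5-fold (95% interval 16.4 to 543) for the others. In the others these 3 genes came almost all from cluster 12, at 242 ± 13.6, 196 ± 5.27 and 146 ± 37.4 CPM. In cluster 4, calls were lost with DESeq2 for Ffar2 (5.35, adjusted p = 0.581), Il12b (-6.14, adjusted p = 0.519) and Ly75 (-5.37, adjusted p = 0.584); at 2000 UMIs per cell for Tnfrsf4 (-4.33, adjusted p = 1) and Il12b (-1.93, adjusted p = 0.985); with count splitting for Tnfrsf4 (-2.24, adjusted p = 0.979) and Ly75 (-3.38, adjusted p = 0.214); without the 5% of cells with the most UMIs for Retnla (6.82, adjusted p = 0.159), Thbs1 (7.64, adjusted p = 0.0795) and Ly75 (-4.19, adjusted p = 0.117); and with 4 libraries as samples for Retnla (7.87, adjusted p = 0.194). The calls of Tnfrsf4 (-7.03, adjusted p = 0.0659) and Il12b (-3.68, adjusted p = 1) were lost without library 1-2, and that of Tnfrsf4 also without library 2-2 (-4.61, adjusted p = 1).

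Several lysosome, MHC class II and matrix genes were higher in cluster 4. Of the lysosome genes, 9 of 17 tested members were higher and 1 lower (10 and 2 adjusted over the list alone), median 0.78, or 0.58 with genes without counts on a side at their bound (adjusted p = 0.00024, and 0.177 with an estimated correlation), a median that was 0.52 with DESeq2. Of the MHC class II genes, 4 of 8 tested members were higher and 0 lower (7 and 0 adjusted over the list alone), median 0.51 (adjusted p = 0.00977, and 0.286 with an estimated correlation). H2-DMb1 had 899 ± 15.2 against 499.7 ± 45.97 CPM (SD, n = 2). Among the matrix genes, 4 of 10 tested members were higher and 1 lower (5 and 1 adjusted over the list alone), median 1.96 (adjusted p = 0.00397, and 0.0801 with an estimated correlation). Tgfbi had 588 ± 61.4 against 157 ± 46.95. Of the complement genes, 3 of 9 tested members were higher and 0 lower (4 and 0 adjusted over the list alone), median 0.62 (adjusted p = 0.0191, and 0.176 with an estimated correlation). The properdin gene Cfp had 431 ± 7.15 against 63.96 ± 4.97. Among the glycolysis genes, 4 of 10 tested members were higher and 0 lower (6 and 0 adjusted over the list alone), median 0.49 (adjusted p = 0.00552, and 0.25 with an estimated correlation). Eno1 had 194 ± 9.34 against 66.6 ± 1.03. Called higher in the fit without clusters 3 and 8, but not with them, were inflammatory cytokine genes at 0.78 (adjusted p = 0.0155) and stress genes at 0.62 (adjusted p = 7.57e-06). Cluster 4 list members lost their calls without the libraries given or in other fits: Ctsd (1-2), Ctsl (1-2), H2-DMb2 (1-2, 2-2, 6 others), H2-Ab1 (1-2), C1qb (1-2, 2-1, 2 others), Adam8 (1 other), Hk2 (1 other), Tpi1 (1-2, 2-1, 2-2, 4 others), Pkm (1-2). In all, cluster 4 had 459 genes higher and 171 lower, or 655 and 149 in the fit without clusters 3 and 8. The counts were 307 higher and 102 lower without library 1-2 and 357 higher and 80 lower without library 2-2.

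Cluster 11, cDC1-like, had more of Clec9a, a receptor for dead cells, at 179 ± 15.04 against 4.06 ± 2.76 CPM (SD, n = 2), and of the integrin gene Itgae at 134 ± 57.1 against 3.94 ± 0.994. P2ry14 had 154 ± 21.7 against 4.46 ± 1.53 and Sept3 175 ± 41.8 against 4.94 ± 2.81. Snx22 and Gcsam had 1 and 3 UMIs in the other dendritic clusters, with pooled ratios of 243-fold (95% interval 41.5 to 9819) and 66.7-fold (95% interval 21.1 to 338). Il7r, Mcemp1 and the actin bundling gene Fscn1 had no UMI, and were at least 14.2-fold, 22.9-fold and 20.2-fold lower, with Fscn1 in the others almost all from cluster 12. Of the stress genes, 7 of 12 tested members were higher and 0 lower (8 and 0 adjusted over the list alone), median 0.75 (adjusted p = 0.015, and 0.396 with an estimated correlation). Btg2 had 2191 ± 498 against 977 ± 199. The cell cycle list was called with 1 of 10 tested members higher (1 adjusted over the list alone), Hmgb2 at 269.7 ± 4.65 against 136 ± 28.6, and a median of 1.53 (adjusted p = 0.0459, and 0.269 with an estimated correlation). The call of Hmgb2 was lost without library 1-2 (0.77, adjusted p = 0.164). In the fit without clusters 3 and 8 the list had adjusted p = 0.0598. There the complement list gained a call, higher, at 0.82 (adjusted p = 0.0193), and the cytokine list, lower, at -0.02 (adjusted p = 0.0165). In cluster 11, calls were lost with DESeq2 for Snx22 (6.79, adjusted p = 0.443), Sept3 (5.38, adjusted p = 0.559) and Itgae (5.02, adjusted p = 0.438); and at 2000 UMIs per cell for Hmgb2 (1.03, adjusted p = 0.162). Cluster 11 list members lost their calls without the libraries given or in other fits: Egr1 (1-1, 2-2, 4 others). In all, cluster 11 had 384 genes higher and 374 lower, or 439 and 379 in the fit without clusters 3 and 8. Counts fell without library 1-2 or 2-2, which left 1 sum.

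Cluster 12, mature-DC-like, had more of Fscn1, at 1434 ± 346 against 1.77 ± 0.114 CPM (SD, n = 2), and of Fabp5, at 8805 ± 828 against 224 ± 71.8. The chemokine gene Ccl5 had 1318 ± 87.2 against 35.9 ± 1.72, and Il12b, which encodes a subunit of interleukin 12, a pooled ratio of 179-fold (95% interval 57.5 to 899.6) over 3 UMIs in the others. Tnfrsf4 and Nudt17 had 1 and 3 UMIs in the others, with pooled ratios of 654-fold (95% interval 113 to 26272) and 218-fold (95% interval 70.8 to 1088). H2-M2, the transcription factor gene Tcf7 and Stap2 had no UMI in the others and were at least 124-fold, 77.8-fold and 54.5-fold higher. Plac8, Sla and Ly6a had none in cluster 12 and were at least 60.8-fold, 7.85-fold and 9.60-fold lower. Of the complement genes, 0 of 9 tested members were higher and 6 lower (0 and 7 adjusted over the list alone), median -1.29 (adjusted p = 0.00661, and 0.128 with an estimated correlation). Among the glycolysis genes, 0 of 10 tested members were higher and 6 lower (0 and 7 adjusted over the list alone), median -0.88 (adjusted p = 0.0125, and 0.275 with an estimated correlation). Among the stress genes, 0 of 12 tested members were higher and 10 lower (0 and 11 adjusted over the list alone), median -1.23 (adjusted p = 0.00539, and 0.324 with an estimated correlation). Examples are Cfp at 15.96 ± 5.62 against 272 ± 11.3, Ldha at 128 ± 44.9 against 435 ± 5.18 and Hspa1a at 447 ± 72.5 against 2071 ± 904. In cluster 12, calls were lost with DESeq2 for Nudt17 (8.06, adjusted p = 0.297), Tcf7 (8.14, adjusted p = 0.296) and Stap2 (7.69, adjusted p = 0.326). Cluster 12 list members lost their calls without the libraries given or in other fits: C4b (1-1, 2-1, 2-2, 5 others), Pgam1 (2-2, 1 other), Gpi1 (1-2, 2-1, 2-2, 2 others). In all, cluster 12 had 576 genes higher and 574 lower, or 569 and 740 in the fit without clusters 3 and 8. Counts fell without library 1-2 or 2-2, which left 1 sum.

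**Figure D4:**
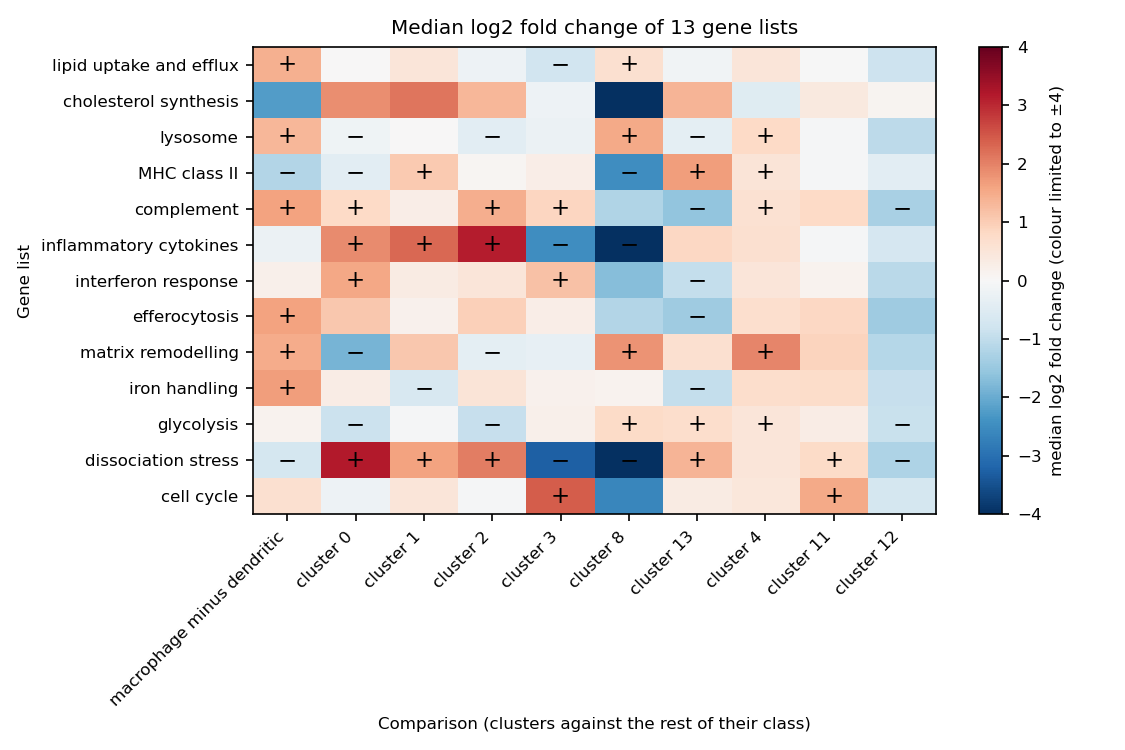
Median log2 fold change (colour) of 13 gene lists (vertical axis) in the 10 comparisons (horizontal axis). Plus and minus signs mark the 57 of 130 pairs that camera called higher or lower with a preset correlation. Without clusters 3 and 8 the median of the stress list has the opposite sign for macrophage minus dendritic and for clusters 1, 2 and 13, at -0.01 for cluster 2.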

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

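Of the tests here, those of depth alone, of free fibroblast RNA and of evenly spread haemoglobin were chosen only after the result was seen. With 1 group of mice, no biological explanation was tested for any pattern.

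In clusters 3 and 8, chemokine and immediate-early transcripts were scarce in shallow cells. Capturing fewer UMIs leaves the expected share of a gene set in the UMIs unchanged, so depth alone is argued against: the mean shares of the stress list and of the cytokine list in clusters 0, 1, 2 and 13 were at least 12.1 times those in cluster 3 or 8 in each replicate. Thinning all cells to 500 UMIs cannot move these shares on average and is no test. A candidate explanation that stays open is loss of the nucleus or of nuclear RNA, since the nuclear RNAs Malat1 and Neat1 lay at no more than 8.39 percent of their cluster 0 level in either cluster and replicate. Cells that differ in kind or in state before the digestion stay open as well.

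Cluster 9 held fibroblast transcripts, which came to 1.74% of its UMIs although the gate on CD45 would remove fibroblasts. Its cells lie outside the comparisons. Free RNA is argued against, which would reach all droplets of a library: the median UMIs of the 6 fibroblast markers in a cell of cluster 9 were at least 86.6 times the mean in the cells of all other clusters in each of the 4 libraries. Droplets with a fibroblast and a leukocyte may be the source: 86.0% of the cells held at least 10 UMIs of the fibroblast list and of the leukocyte genes Ptprc, Tyrobp, Fcer1g, Lyz2 and Cd74, against 0.315% in cluster 0. Median UMIs were higher than in cluster 0 in 3 libraries but not in library 2-1 (4441.5 against 7285), so such droplets and cells that make both cannot be told apart.

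Haemoglobin transcripts stood out in clusters 3 and 7. Free RNA spread evenly over droplets is argued against for nearly all of them, since 99.04% of the haemoglobin UMIs of cluster 3, and more of those of cluster 7, lay in 1 cell. It stays open for the rest, 33 UMIs in the other 324 cells of cluster 3, beside 12 in the 105 cells of cluster 8. A single cell held 3400 of 3433 in cluster 3 and another 3367 of 3376 in cluster 7. Droplets that also caught red blood cells may account for these 2 cells, which held at least 46 UMIs of the 5 leukocyte genes as well.

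Between macrophage and dendritic clusters 1939 genes were called. Of the 84 ways to divide the 9 clusters into 6 and 3, 16 gave as many genes, the real one included. The highest other gave 2820. All 15 others kept clusters 3 and 8 on one side. Each division contrasts different clusters, so these counts cannot test chance.

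The share of cluster 6 stood far from the others in 1 library: it was 6.34% in library 1-2 (95% interval 5.04% to 7.85%), and the gap to the next library took 0.886 of the whole range. Of 22 groups of 4 libraries looked at in this way 1 lay beyond the critical value of 0.829, and chance gives about 1 in 20. In data outside the comparisons, monocyte markers were 0.426% of the UMIs of cluster 5 and neutrophil markers 2.14% of those of cluster 7. In cluster 6, proliferation markers were 0.383% of the UMIs and T cell markers 0.0313%. Mast cell markers were 0.102% of the UMIs of cluster 10, where 1 cell held 77 UMIs of mast cell genes.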

How the results depend on the processing

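The fit without clusters 3 and 8 was chosen only after the result was seen. Of the values of named genes under all alternatives, 3962 kept direction and side of the threshold, 244 lost the call and 17 reversed; for lists these were 589, 88 and 3, and 64 gained a call. Counts of genes and of called lists stayed within 1.5 times in 221 cases and moved in 59, and shares moved by more than their SD in 9 cases and not in 75. Causes of these moves were not tested, but fewer cells, genes or sums enter some fits. Of 90 calls of named genes lost without a library, 30 had an adjusted p over 0.9, and 29 of these had a cluster left at 0 counts. Leaving out library 1-2 left 14 sums and library 2-2 left 15. Thinned cells gave no value for cluster 8, so means there lack it, and count splitting none for the cholesterol synthesis list.

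Without the replicate block 309 results of named genes kept direction and side of the threshold and 4 lost their call, and no count moved by more than 1.5 times; 732 genes were higher and 1191 lower between the classes. The 4 libraries with a library block moved no count either. Only genes at 50 CPM and leaving out the 5% of cells with the most UMIs moved none. With an estimated correlation 0 lists were called and with fry 89. DESeq2 gave 74 lower genes for cluster 1, 163 higher for cluster 3, 528 lower for cluster 8 and 371 lower for cluster 12. DESeq2 size factors gave 153 higher for cluster 3. With no filter 1971, 1399 and 1668 genes were higher in clusters 0, 1 and 2. At 2000 UMIs per cell the counts higher and lower were 442 and 341 between the classes, 540 and 28 in cluster 0, 578 and 36 in cluster 2, 23 and 170 in cluster 3, 118 and 126 in cluster 13, 126 and 142 in cluster 11, and 233 and 327 in cluster 12. At that depth 492 were higher in cluster 1 and 27 lower in cluster 4.

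Count splitting gave 481 higher and 793 lower between the classes, 154 and 183 in cluster 3, 410 and 124 in cluster 13, and 361 and 374 in cluster 12. It gave 734 higher in cluster 0, 473 lower in cluster 8 and 215 lower in cluster 11. Without clusters 3 and 8 the counts were 1568 higher between the classes, 480 higher and 236 lower in cluster 0, 363 and 154 in cluster 1, 409 higher in cluster 2 and 598 lower in cluster 13. Among cells with at least 1000 genes the shares were 25.3, 23.5, 14.8, 0.529, 11.1, 8.87, 1.68, 0.242 and 0.0782 percent in clusters 0, 1, 2, 3, 4, 5, 7, 8 and 10.

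Leaving out each library, the counts higher and lower were 466 to 669 and 736 to 1094 between the classes, 988 to 1250 and 92 to 114 in cluster 0, 767 to 992 and 28 to 41 in cluster 1, 944 to 1280 and 145 to 165 in cluster 2, 226 to 282 and 187 to 264 in cluster 3, 226 to 316 and 376 to 836 in cluster 8, 346 to 638 and 106 to 224 in cluster 13, 307 to 401 and 80 to 162 in cluster 4, 228 to 363 and 184 to 344 in cluster 11 and 330 to 514 and 269 to 478 in cluster 12. Counts moved by over 1.5 times without library 1-2 (466 higher between the classes, 376 lower in cluster 8, 346 and 106 in cluster 13, 102 lower in cluster 4, 244 and 219 in cluster 11, 373 lower in cluster 12). They moved without library 2-2 (736 lower between the classes, 80 lower in cluster 4, 228 and 184 in cluster 11, 330 and 269 in cluster 12) and without library 2-1 (545 lower in cluster 8). Shares of clusters 0 to 13 ran, in order, from 18.6 to 22.1, 16.97 to 19.7, 11.2 to 11.9, 10.7 to 13.9, 8.32 to 9.05, 6.64 to 7.45, 3.14 to 4.26, 3.40 to 4.59, 3.18 to 4.24, 2.93 to 3.72, 2.45 to 2.58, 1.27 to 1.61, 1.28 to 1.64, 1.09 to 1.55 percent.

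Reversed log2 fold changes without clusters 3 and 8 were, between the classes, Malat1 0.0213 (adjusted p = 0.88), Neat1 0.89 (adjusted p = 4.5e-09) and Btg2 0.31 (adjusted p = 0.00474); in cluster 0, Tnfaip3 -0.33 (adjusted p = 0.0665), Tnf -0.0248 (adjusted p = 0.952) and Hk2 -0.32 (adjusted p = 0.223); in cluster 1, Tnfaip3 -0.21 (adjusted p = 0.347), Ftl1 0.0921 (adjusted p = 0.723), Hspa1b -0.0533 (adjusted p = 0.885), Fosb -0.032 (adjusted p = 0.932) and Fos -0.23 (adjusted p = 0.342); and in cluster 13, Fosb -0.59 (adjusted p = 0.00327). The stress list reversed there too, at adjusted p = 2.89e-07 between the classes, 5.87e-07 in cluster 1 and 5.72e-08 in cluster 13. At 2000 UMIs, Ftl1 in cluster 1 had 0.17 (adjusted p = 0.438) and Irf7 in cluster 13 0.80 (adjusted p = 0.985). Without library 2-2 Itgax had 0.70 (adjusted p = 0.967) between the classes, where leaving out each library gave -1.78 to 0.70. Without library 1-2 C1qb had -0.0823 (adjusted p = 0.909) in cluster 4, where the highest value, without library 2-2, was 1.33. Leaving out the 5% of cells with the most UMIs, C4b had 0.21 (adjusted p = 0.868) in cluster 12. Depth limits clusters 3, 8 and 10 most.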

Other observations

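The clusters and cells below were described after their values were seen, with no test. Cluster 5, monocyte-like, led with the monocyte markers Chil3, Ly6c2, Plac8 and F10. Chil3, a chitinase-like protein gene, had 285 ± 35.5 CPM (SD, n = 2 biological replicates), Ly6c2, a surface marker of inflammatory monocytes, 358 ± 56.8, and F10, the gene of coagulation factor X, 345 ± 73.5. The thrombospondin gene Thbs1 had 2066 ± 549.5 and Plac8 1751 ± 337. Cluster 6 led with genes of cell division, such as Top2a at 555 ± 86.03, Mki67 at 675 ± 107 and Stmn1 at 1149 ± 39.6. Genes of T and NK cells had 685 UMIs in 43 of its 135 cells.

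Cluster 7, neutrophil-like, led with the alarmin genes S100a9 at 15303 ± 10016 CPM (SD, n = 2) and S100a8 at 6672 ± 3079, followed by G0s2 at 3375 ± 1017 and Hdc, the histamine-forming enzyme gene, at 1362 ± 186. Besides Dcn, cluster 9 led with the matrix genes Mgp at 11440.5 ± 5578, Mmp3 at 2431 ± 755 and Col1a1 at 1343 ± 451. Mast cell genes had 77 UMIs in 1 cell of cluster 10 and 473 in 1 cell of cluster 11. Single cells held 4345 of the 4409 haemoglobin UMIs of cluster 0 and 7000 of the 7078 of cluster 1.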
